A study of Mus musculus with 3 samples.

How the data were processed

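CUT&Tag libraries of Pan02 cells were compared through their peak lists: Flag in POH1-Flag cells, MYC in vector cells and MYC in POH1-Flag cells, with 1 library per group as the sample titles give it. Per the labels' protocols, libraries were made with a commercial transposase kit. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.6, BWA 0.7.17-r1188 and MACS2 2.2.7.1 and the build GRCm38/mm10, with no role, order or parameters. A control library, the handling of duplicate reads and any blacklist are not given in the sources used here. Each library has its own deposited list, so peaks were called per library and not on pooled reads.

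The deposited lists have no header line and follow the narrowPeak layout. The authors' fold enrichment, a linear ratio, and the authors' −log10 p and −log10 q are those of each peak's summit against its background. The deposited score is 10 times the −log10 q, truncated, in nearly all peaks. Peak starts, ends and summit offsets are deposited in bp. The smallest deposited −log10 q was 1.36 for Flag and 1.30 for both MYC lists, which matches a q threshold of 0.05. Fold and q were used to describe, rank or filter peaks within a list, and never compared between lists as a change.

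The whole read pileup k at each summit and its background λ were solved from fold = (k + 1)/(λ + 1) and the Poisson tail probability of more than k reads. The equations gave a whole k for 100% of peaks in each of the 3 lists, within a tolerance of 0.01 of a read step. The solved λ fell on whole-read steps of a window of 10000 bp in the same library, with the smallest peak width (233, 219 and 202 bp) as the fragment length, so the background came from the library itself. The lowest λ, 0.946 for Flag, 0.845 for MYC in vector cells and 0.826 for MYC in POH1-Flag cells, was taken as the genome-wide background. Divided by fragment length it gave 4.06, 3.86 and 4.09 reads per kb, a relative depth of 1.05, 1 and 1.06. Total reads are not given in the sources used here. Median pileups were 15, 14 and 15 reads, so a single peak carries wide counting error. Ratios of pileups between the MYC lists, divided by the genome-wide background, have exact conditional Poisson 95% intervals, and medians over sites have order-statistic intervals. All intervals cover counting error only. PCR duplicates that were kept would make them too narrow.

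Overlap meant at least 1 bp shared. Shares carry Wilson 95% intervals and are set beside 1000 random placements of the list on its own chromosomes. Shared MYC sites were pairs of peaks that were each other's highest overlapping partner. Genes came from a RefSeq table of GRCm38.p6 that gives start and end of 21887 protein-coding genes on chromosomes 1 to 19, X and Y, without strand, exons or sequence. The planned promoter was therefore replaced by a summit within 1 kb of either gene end, exon, intron and UTR classes by inside a gene or elsewhere, and motif searches, GC matching of promoters and removal of repeats were not run. A peak between neighbouring genes counts for each. Peaks on unplaced contigs (108, 224 and 369) and on the mitochondrial genome (5, 4 and 4) stayed in the lists but near no gene.

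The 24 gene lists held 791 entries, of which 790 matched the table, 754 by symbol and 36 by a synonym. For each library, members with a gene-end peak were compared with all genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 72 tests, and for genes gained in POH1-Flag cells over 24 tests among genes without a vector peak. Members were also compared with 10000 random lists, unmatched or matched on gene length. These describe the libraries, since genes are not replicates. The difference between Flag overlaps was tested by an exact McNemar test, two-sided. No test between cell lines was possible.

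Named genes followed a rule. It took Myc, Psmd14, Max, Cdkn1a and E2f1, the 8 genes with the largest −log10 q near an end in each library, in each direction of the MYC comparison, in all 3 libraries and in Flag alone, and the 4 strongest members of each list in POH1-Flag MYC, leaving out predicted genes. A gene chosen by this rule is not reported here. The groups, lists, naming rule, tests and the alternatives to each choice were fixed before the data were examined. The gene-end rule, the ratio of recovered pileups between the MYC lists with its scalings, the length-matched lists the MYC lists without peaks that meet a Flag peak, and the count of gained genes whose peak meets a vector peak were added afterwards. Alternatives were stricter thresholds, other overlap rules, equal list lengths, chromosomes 1 to 19 and X alone, wider gene-end rules, thinning of the POH1-Flag MYC list to the vector depth (20 draws), other pileup scalings, and MYC lists without peaks that meet a Flag peak.

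The steps were tested on simulated data. Of 5000 simulated pileups 100% were recovered, a planted overlap of 60% in 4000 peaks came back as 60%, and a list thinned from 40000 simulated sites was 1.00 times as long as one drawn at the lower depth. All 5 planted gene lists and 0 of 19 unplanted lists were called over 21887 genes. A planted log2 pileup ratio of 0.7 at 20000 sites came back as 0.63 among sites called in both lists, and a ratio of 0 as 0. Of 1000 simulated 95% ratio intervals 96.3% held the true value. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.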

Results

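Signal from antibodies against the transcription factor MYC and against the Flag tag of POH1-Flag was mapped in Pan02 cells, a line from a mouse pancreatic ductal adenocarcinoma. POH1, encoded by Psmd14, is the deubiquitinase of the proteasome lid. The assay was CUT&Tag, in which an antibody brings a transposase to its target protein and the DNA beside it is cut and tagged for sequencing. There were 3 libraries, with 1 library per group: Flag in cells that stably carry POH1-Flag, MYC in cells with the empty vector, and MYC in the POH1-Flag cells. No group had a replicate, so intervals cover counting error within a library, and no difference between cell lines could be set against a spread between replicates. The series title presents POH1 as a regulator of MYC. The design allows 2 questions to be asked: where MYC peaks lay with and without POH1-Flag, and whether Flag peaks lay at sites of MYC. The depth implied by the genome-wide background was close in the 3 libraries, at 1.05 for Flag and 1.06 for MYC in POH1-Flag cells relative to MYC in vector cells. Positions are on GRCm38. A peak is called near a gene end when its summit lies within 1 kb of either end of a protein-coding gene, because strand was not used.

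In vector cells 16 of the 24 gene lists had MYC peaks near a gene end more often than all genes, and 11 did so at a −log10 q of at least 5, 10 at a fold of at least 5 and 9 at a −log10 q of at least 10. At 1 or more of these limits the call was lost for the mesenchymal, YAP and AP-1 list, pancreatic cancer drivers, cell cycle genes, histones, the mitochondrial ribosome, oxidative phosphorylation, p53 targets and the proteasome. The highest shares were 35 of 38 genes for tRNA synthetases and translation factors, 31 of 35 histone genes (linker histones included), 21 of 25 genes of the unfolded protein and ATF4 responses, 41 of 50 core MYC targets, 60 of 78 ribosomal protein genes and 44 of 60 ribosome biogenesis genes. The lists above all genes also included deubiquitinases (26 of 43), p53 targets (15 of 25) and mesenchymal, YAP and AP-1 genes (18 of 32). Over all protein-coding genes the share was 28.2% (6172 of 21887, Wilson 95% interval 27.6 to 28.8%). The adjusted p in Fisher's exact test was 3.12e-15 for the translation list, 1.14e-12 for the histones, 5.19e-08 for the stress response list, 4.43e-14 for the core targets, 1.96e-17 for the ribosomal proteins and 4.13e-12 for ribosome biogenesis, and 3.30e-05, 0.00263 and 0.00263 for the last 3 lists. Below all genes in Fisher's exact test were acinar (0 of 20, adjusted p = 0.00421), fibroblast (0 of 15, 0.0164), T cell (0 of 15, 0.0164), olfactory receptor (0 of 24, 0.00120) and neuronal genes (0 of 15, 0.0164). Macrophage genes (1 of 15, Cd14, 0.130) and ductal genes (3 of 15, 0.834) did not pass the exact test, though their shares (6.67% and 20%) were below that of all genes. With a −log10 q of at least 5, or a fold of at least 5, only the acinar and olfactory lists stayed below all genes in this test. At a −log10 q of at least 10 no list did.

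The vector list held 12175 peaks over 5.52 Mb, with a median width of 398 bp and a median of the authors' fold enrichment of 5.29. Near a gene end lay 44.4% of them (5401 peaks, 43.5 to 45.2%), against 3.17% for peaks placed at random on the same chromosomes. A further 25.3% lay inside a gene and 30.4% elsewhere. By the authors' −log10 q, the strongest gene-end peaks lay at Wls, which carries Wnt proteins to the cell surface (76.6), Ppp1r15b, a regulator of eIF2α dephosphorylation (40.03), the mitochondrial leucyl-tRNA synthetase gene Lars2 (37.5), Saysd1 (35.6), Brat1 (35.5), the neighbouring genes Hdgfl2 and Ubxn6 (35.2) and Xpot, which exports tRNA from the nucleus (33.5). Summits at Ppp1r15b and Xpot were 35 and 83 bp from the gene end, whereas those at Wls and Lars2 were 880 and 684 bp away. Wls and Lars2 also had Flag peaks, of 96 and 29 reads against 81 and 45 in this MYC library. Peaks there were thus not particular to the MYC antibody. At Myc itself (chromosome 15, 61985341 to 61990361) the peak was weak, with a pileup of 13 reads at a summit 75 bp from the gene end. Max, the partner of MYC (chromosome 12, 76937269 to 76962323), had a pileup of 28 reads.

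**Figure D1:**
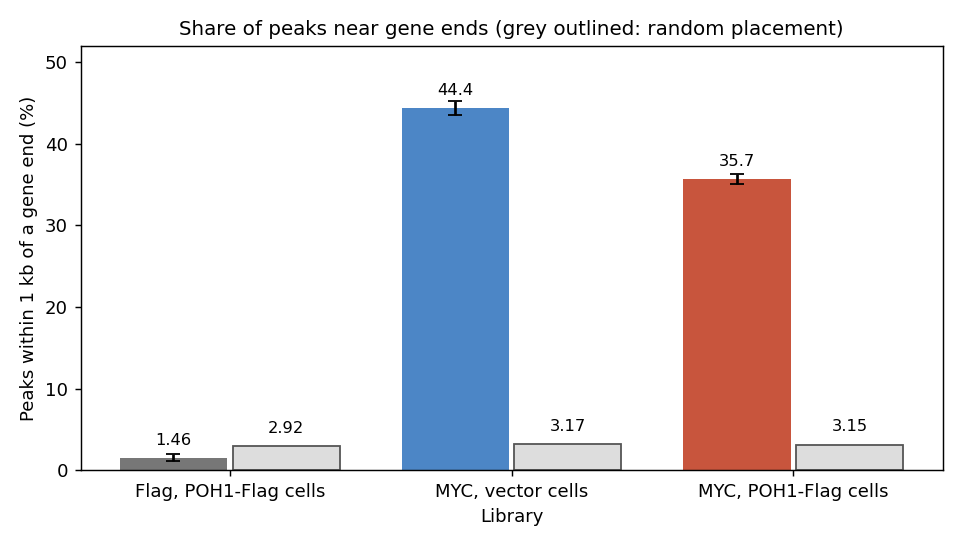
Share of peaks whose summit lies within 1 kb of a gene end, in percent of each library's peaks, with Wilson 95% intervals as error bars, beside the mean share of 1000 random placements (outlined grey bars). MYC reached 44.4% and 35.7%, and Flag 1.46%.

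In POH1-Flag cells MYC peaks were more numerous, and 98.0% of the genes with a vector peak near an end (6049 of 6172) had one again. The list held 22647 peaks over 11.2 Mb, against 12175 over 5.52 Mb. Genes with a gene-end peak numbered 8755 (40%, 39.4 to 40.7%), of which 2706 had none in vector cells, while 123 genes had one in vector cells only. Psmd14, the gene of POH1 (chromosome 2, 61711694 to 61800376), was among the genes with a peak in POH1-Flag cells only. Its summit lay 177 bp from the gene end with a pileup of 24 reads, and neither other library had a peak anywhere in the gene.

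Of the vector peaks, 84.7% (10313 of 12175, 84.1 to 85.3%) overlapped a peak of the POH1-Flag cells by at least 1 bp, and 45.1% of the POH1-Flag peaks (10219 of 22647, 44.5 to 45.8%) overlapped a vector peak. Random placement gave 0.865% and 0.461%. Peaks missing from the other list were weaker in their own than shared peaks. Median pileups were 10 against 15 reads in vector cells and 12 against 23 in POH1-Flag cells. With each list split by −log10 q into 10 bins of equal size, 63.8% of the weakest bin of the vector list were found in POH1-Flag cells and 98.5% of the strongest. In the POH1-Flag list the shares ran from 9.01% to 98.5%. Scaled to the vector background, 12288 of the 12428 POH1-Flag MYC peaks without a vector partner (98.9%) would have passed the lowest −log10 p of the vector list. The median was 12.3 reads against 8 needed. These peaks had already passed a q limit of 0.05 in their own list, at a similar background. Such a high share was therefore close to fixed in advance. It does not tell why the vector list lacks them. The 12428 peaks of POH1-Flag cells without a vector partner were less often near a gene end (23.0%, 22.2 to 23.7%) than the shared peaks of that list (51.2%, 50.2 to 52.1%), and the 1862 vector peaks without a partner still less often (7.14%, 6.06 to 8.40%). The share of all peaks near a gene end was accordingly lower in POH1-Flag than in vector cells, at 35.7% against 44.4%. The order held at a −log10 q of at least 5 (46.7% against 50.8%) and at a fold of at least 5 (46.6% against 51.2%). At a −log10 q of at least 10 it was not seen, with 58.6% (57.4 to 59.8%) against 56.6% (54.5 to 58.6%).

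**Figure D2:**
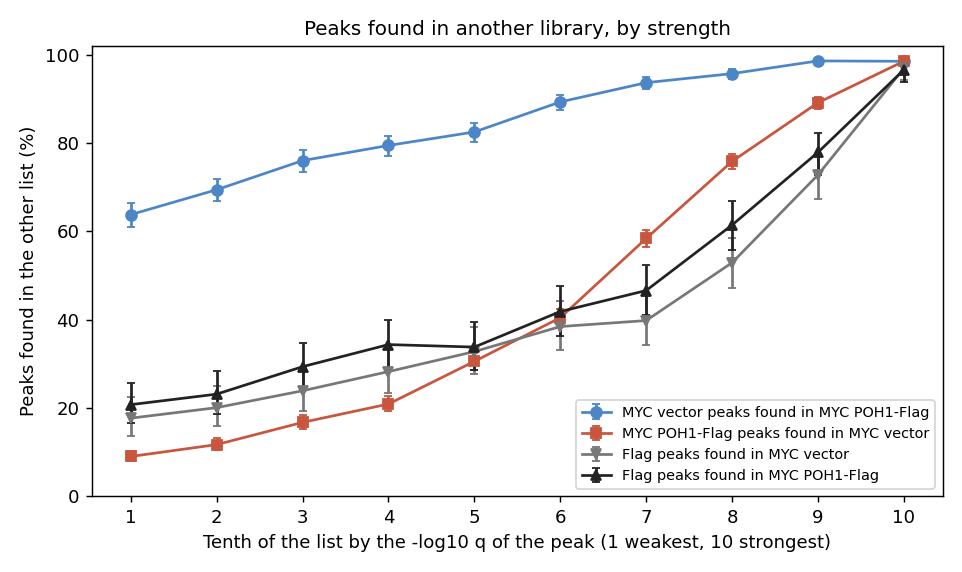
Percent of peaks found in another library, in 10 equal bins of the list ranked on the authors' −log10 q (1 weakest, 10 strongest), with Wilson 95% intervals. All 4 comparisons reached at least 96.6% in the strongest bin, and in the weakest bin they ran from 9.01% to 63.8%.

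Read pileups at the summits, solved from the authors' fold enrichment and −log10 p, were higher in POH1-Flag cells at shared gene-end sites. Each pileup was divided by the genome-wide background of its library, and the authors' fold values themselves were not set against each other. At 5126 shared MYC peaks near a gene end and without a Flag peak, the median log2 ratio of POH1-Flag to vector cells was 0.71 (0.70 to 0.72), a fold of 1.64, and 98.3% of these sites were higher in POH1-Flag cells. Farther from gene ends, 4036 shared sites without a Flag peak had a median of 0.59 (0.57 to 0.62). At 898 shared sites with a Flag peak the median was −0.05 (−0.08 to 0.01), and at the 22 of them near a gene end it was 0.23 (0.06 to 0.70). With pileups scaled by reads alone the medians were 0.59 near gene ends and −0.17 at sites with a Flag peak.

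**Figure D3:**
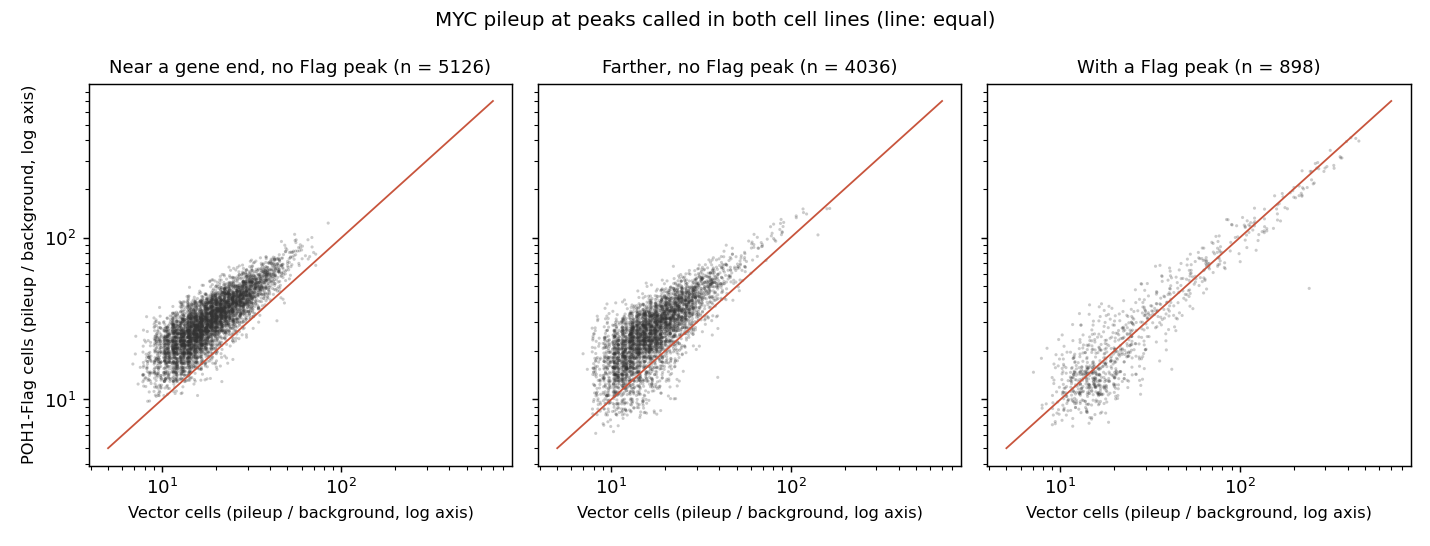
MYC read pileup over the genome-wide background at peaks called in both cell lines, on log axes, vector cells against POH1-Flag cells, 1 point per site with a small random shift. Sites without a Flag peak lie mostly above the line of equality (medians 0.71 and 0.59 on the log2 scale), and sites with one lie around it (−0.05).

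Genes named for strong peaks in the POH1-Flag list, a choice that favours high ratios, had a ratio of POH1-Flag to vector cells above 1 with its 95% counting interval at Eif5a, a translation factor and known MYC target (39 and 78 reads, ratio 2.05, 1.38 to 3.09), at the nucleolin gene Ncl (47 and 80 reads, 1.74, 1.20 to 2.55), at Hdgf (46 and 87 reads, 1.93, 1.34 to 2.83), at Tbl2 (41 and 74 reads, 1.85, 1.24 to 2.77) and at Adss, an enzyme of AMP synthesis (32 and 63 reads, 2.01, 1.296 to 3.19). Wls (1.24, 0.913 to 1.68), Lars2 (1.27, 0.845 to 1.93) and Saysd1 (1.38, 0.9499 to 2.03) were also among the 8 strongest genes of that list. Their intervals held 1. E2f1, a driver of S phase entry, had 16 and 31 reads (1.98, 1.05 to 3.88). At Myc (13 and 20 reads, 1.57, 0.745 to 3.44) and Max (28 and 39 reads, 1.42, 0.855 to 2.40) a difference was not detectable at this depth. Among the genes named for the strongest vector peaks, a choice that favours low ratios, no interval excluded 1. The ratio was 1.38 (0.9499 to 2.03) at Saysd1, 1.27 at Brat1, 1.27 at Lars2, 1.24 at Wls, 1.16 at Xpot, 1.13 at Hdgfl2 and Ubxn6, and 0.939 (61 and 56 reads, 0.642 to 1.37) at Ppp1r15b. Cdkn1a, which encodes the cell cycle inhibitor p21, had no peak near either end in any of the 3 libraries.

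Genes marked in POH1-Flag cells only were more frequent in 12 of the 24 lists than among all genes. Of the 15715 genes without a vector peak near an end, 17.2% had one in POH1-Flag cells. For cell cycle and E2F genes it was 15 of 18, for nucleotide and folate-linked synthesis 9 of 10, for p53 targets 8 of 10, for ribosome biogenesis 12 of 16, for the proteasome 15 of 22, for oxidative phosphorylation 14 of 22, for ribosomal proteins 11 of 18 and for the mitochondrial ribosome 13 of 23. Fisher's exact test with adjustment over 24 lists gave 3.89e-08 for the cell cycle list, 6.68e-06 for nucleotide synthesis, 8.49e-05 for both p53 targets and the mitochondrial ribosome, 4.87e-06 for ribosome biogenesis, 2.02e-06 for the proteasome, 7.49e-06 for oxidative phosphorylation and 1.12e-04 for ribosomal proteins. Core MYC targets (6 of 9, adjusted p = 0.00361), pancreatic cancer drivers (5 of 8, 0.0128), deubiquitinases (7 of 17, 0.0380) and the list of mesenchymal, YAP and AP-1 genes (6 of 14, 0.0443) also passed in Fisher's exact test. The test compares genes within these libraries, and genes are not replicates. The 15715 genes include lists without a MYC peak in either cell line, such as T cell and neuronal genes, and promoter GC was not matched. A pass therefore does not show that the gain was particular to a list. Glycolysis (6 of 15, 0.0543), histones (2 of 4, 0.176), stress response genes (2 of 4, 0.176), translation factors (1 of 3, 0.519) and the MYC network (2 of 12, 1.0) did not pass. Olfactory receptor genes were gained less often than all genes (0 of 24, Fisher's exact adjusted p = 0.0463). At 33 of the 2706 genes the POH1-Flag peak overlapped a vector peak whose summit lay beyond 1 kb, and without these genes the number of lists that passed was again 12.

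In POH1-Flag cells the proteasome list thereby reached 38 of 45 genes, from 23 in vector cells, and the cell cycle list 44 of 48, from 30. Proteasome genes with a peak in both lists had a median log2 pileup ratio of 0.74, and the ratio was above 0 at all 23 of them. This was close to the median of 0.71 over all 5126 shared gene-end sites without a Flag peak, of which 98.3% were higher. List medians lay on both sides of that value, as with oxidative phosphorylation (0.62) and p53 targets (0.88). Genes named here and in the lists below were the strongest members in POH1-Flag cells, a choice that again favours high ratios. For the proteasome they are the activator subunit genes Psme2 (21 and 42 reads, ratio 2.05, 1.18 to 3.64) and Psme3 (25 and 39 reads, 1.596, 0.942 to 2.75), Psmd12 of the lid (11 and 26 reads, 2.42, 1.15 to 5.42) and Psma4 of the core particle (12 and 28 reads, 2.39, 1.18 to 5.15). Cell cycle genes had a median of 0.87 over 29 shared genes, with Wee1, a kinase that restrains mitosis, at 26 and 50 reads (1.97, 1.20 to 3.29), the replication factor gene Gins2 at 18 and 33 reads (1.88, 1.03 to 3.54) and Cdk4 at 27 and 42 reads (1.59, 0.958 to 2.68). Ccne2, the cyclin E2 gene, counts as gained only through the 1 kb limit. Its peak of 56 reads, 978 bp from the gene end, overlapped a vector peak of 36 reads at 1048 bp (ratio 1.59, 1.03 to 2.49).

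Nucleotide synthesis genes with a peak rose in number from 22 to 31 of 32, among them the purine enzyme gene Atic (31 and 57 reads, ratio 1.88, 1.19 to 3.01) and Paics and Ppat, which face each other and share a site (35 and 52 reads, 1.52, 0.971 to 2.40). Ribosome biogenesis genes rose in number from 44 to 56 of 60 and had a median log2 ratio of 0.81 at 44 shared genes, with Utp15 at 12 and 34 reads (2.90, 1.46 to 6.15) and Heatr1 at 15 and 35 reads (2.39, 1.27 to 4.70). Ribosomal proteins rose from 60 to 71 of 78 genes, with a median of 0.71 over 60 shared genes. Oxidative phosphorylation rose from 22 to 36 of 44 genes, with the complex I gene Ndufb5 at 18 and 48 reads (2.73, 1.56 to 4.98) and the cytochrome c gene Cycs at 25 and 40 reads (1.64, 0.969 to 2.82), and the mitochondrial ribosome from 19 to 32 of 42. Among p53 targets, 15 and 23 of 25 genes had a peak, and the DNA repair gene Xpc (19 and 41 reads, 2.21, 1.25 to 4.03) and Sesn1 (17 and 41 reads, 2.47, 1.37 to 4.63) were examples. Deubiquitinase genes with a peak numbered 26 and 33 of 43, including Usp36, which is known to deubiquitinate MYC (29 and 49 reads, 1.73, 1.07 to 2.84), Usp28 (22 and 45 reads, 2.09, 1.23 to 3.66) and Usp22 (32 and 49 reads, 1.57, 0.983 to 2.53).

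Counts for the remaining lists follow. Of these, core MYC targets, cancer drivers and mesenchymal, YAP and AP-1 genes exceeded all genes in the test of gained genes. Core MYC targets went from 41 to 47 of 50 genes, with a median log2 ratio of 0.66. Translation factors went from 35 to 36 of 38 genes, histones from 31 to 33 of 35 with a median log2 ratio of 0.28, and stress response genes from 21 to 23 of 25 with a median of 0.43. The MYC network went from 16 to 18 of 28 genes, with Mxd4, a repressor that pairs with MAX, at 26 and 59 reads (2.32, 1.44 to 3.84) and Mlxip at 36 and 46 reads (1.31, 0.827 to 2.08). Pancreatic cancer drivers went from 12 to 16 of 20, and mesenchymal, YAP and AP-1 genes from 18 to 24 of 32. Glycolysis genes went from 9 to 15 of 24, which did not exceed all genes in Fisher's exact test in either cell line (adjusted p = 0.545 and 0.0586). Fibroblast genes stayed below all genes in POH1-Flag cells in the exact test (1 of 15, Pdgfrb, adjusted p = 0.0138), but not at a −log10 q of at least 10 (0.119). Ductal genes (4 of 15, 0.632) and macrophage genes (2 of 15, 0.0596) did not pass. Their shares (26.7% and 13.3%) were below the 40% of all genes, and lists of 15 genes leave a difference open. Acinar, T cell, olfactory and neuronal genes stayed at 0. In each cell line 16 of the 24 lists stood above all genes at an adjusted p under 0.05. With a −log10 q of at least 10 there were 11 in POH1-Flag cells. Lost there were p53 targets, oxidative phosphorylation, the mitochondrial ribosome, cancer drivers and the mesenchymal, YAP and AP-1 list. With a fold of at least 5 there were 13 in POH1-Flag cells, without histones, cancer drivers and the mesenchymal, YAP and AP-1 list.

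**Figure D4:**
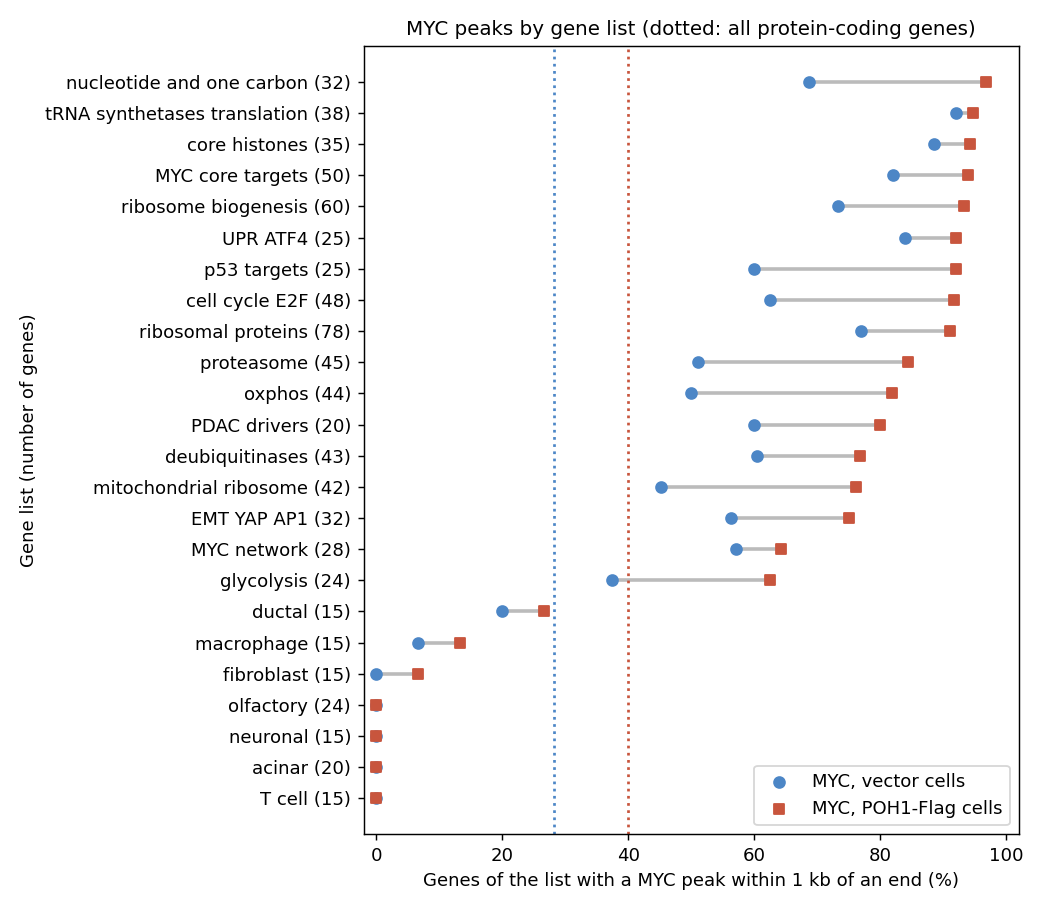
Percent of the genes of each fixed list that have a MYC peak within 1 kb of an end, in vector cells (circles) and POH1-Flag cells (squares); dotted lines give all protein-coding genes (28.2% and 40%). In each cell line 16 of the 24 lists exceed all genes by Fisher's exact test, and the acinar, T cell, olfactory and neuronal lists lie at 0. The list labelled core histones also holds linker histone genes.

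Among the strongest gene-end peaks of POH1-Flag cells that met no vector peak were those at Cox7a2l, a factor of respiratory supercomplex assembly (−log10 q 21.5), at the site between Blvrb and Sptbn4 (20.6), at Zfp619 (20.3), at the site shared by Rnft2 and Spring1 (19.5) and at Gnl3l (18.6). In the other direction, values in the vector list were 14.7 at Lypd4, 7.53 at Them7, 7.25 at the vomeronasal receptor gene Vmn1r48, 6.72 at the site shared by Ftsj3 and Psmc5, 6.40 at Pla2g6 and 6.23 at the site shared by the heat shock genes Hspa1a and Hspa1l. Lypd4 and Them7 also had a Flag peak, and Ftsj3, Psmc5 and Pla2g6 had another peak near an end in POH1-Flag cells.

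Few peaks of the Flag library lay near a gene end. The Flag list held 2936 peaks over 1.08 Mb, with a median width of 315 bp and a median fold of 5.25. Only 1.46% of them (43 peaks, 1.09 to 1.97%) were near a gene end, below the 2.92% of random placement, and 65.7% were neither near nor inside a gene. At a −log10 q of at least 10 the share near a gene end was 3.13% (1.91 to 5.10%), which is not below the placement of the whole list. Peaks of the whole Flag list touched the ends of 43 protein-coding genes. Of these, 30 also had a MYC peak near an end in vector cells (odds ratio 5.90, Fisher's exact p = 1.83e-08) and 32 in POH1-Flag cells (odds ratio 4.38, exact p = 5.97e-06). Of the fixed lists, 1 ribosomal protein gene (Rps29) and 1 translation gene (Eef1a1) were among them, and no other list had a member. Neither the Myc nor the Psmd14 gene had a Flag peak near an end.

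By −log10 q the leading Flag peaks near gene ends were at Wls (94.5), Kdm1a, which encodes a histone demethylase (22.6), Lars2 (20.6), Oasl1 (20.1), Adgb (19.7), Asmt (13.2), Them7 (12.7), Rps29 (12.7) and Polr3gl (12.3). All of these except Them7, which lacked a peak in the MYC library of POH1-Flag cells, had a gene-end peak in all 3 libraries, as did 26 of the 43 genes. Another 7 genes had a Flag peak only, with Olfr270 (7.41), Speer4c (4.56), Wap (3.61) and Frmd4a (3.37) as the named ones. Outside gene ends, each of the 10 strongest Flag peaks overlapped peaks in both MYC libraries. The strongest of all, at chromosome 11, 89081617 to 89082164 inside a gene, had a pileup of 285 reads, and that at chromosome 9, 35305141 to 35305715 had 281.

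Flag peaks overlapped MYC peaks far more than placement gives, but seldom at MYC's gene-end sites. Of the 2936 Flag peaks, 42.3% (40.6 to 44.1%) overlapped a MYC peak of vector cells and 46.6% (44.8 to 48.4%) one of POH1-Flag cells, against 0.382% and 0.724% at random. Both lists were met by 912 Flag peaks, the vector list alone by 331, the POH1-Flag list alone by 455, and neither by 1238. The exact McNemar p of 331 against 455 was 1.10e-05, which compares libraries and not conditions. The order depended on the lists compared. Against the strongest MYC peaks in numbers equal to the Flag list, 14.3% of Flag peaks met vector and 8.86% POH1-Flag sites. From the MYC side, 27 of 5401 vector peaks near a gene end (0.4999%, 0.344 to 0.726%) and 30 of 8081 in POH1-Flag cells (0.371%, 0.260 to 0.529%) met a Flag peak. Farther from gene ends, 18.0% of vector and 9.19% of POH1-Flag MYC peaks did. Among the 1000 strongest gene-end MYC peaks, 10 in vector and 8 in POH1-Flag cells met a Flag peak. At 1230 sites shared by Flag and vector MYC, pileups over background were alike, with a median log2 ratio of Flag to MYC of 0.16 (0.12 to 0.18). The vector cells carry the empty vector in place of POH1-Flag, and Flag in vector cells was not analysed here.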

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

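The tests without MYC peaks that meet a Flag peak, with pileups scaled by reads alone, with pileups scaled to shared sites that meet a Flag peak, with random lists matched on gene length, and without gained genes whose peak meets a vector peak were chosen after the result was seen. No tested setting changed the direction of the pileup ratio near gene ends or the order of the MYC peak numbers. Another 55 values stayed near the reported ones, which for a count means within 1.5 times it and for a share or median within its 95% interval. That bound is wide for counts, as with the gene lists above all genes in vector cells, 11 against 16 at a −log10 q of at least 5. The 55 include the 2673 gained genes and 12 lists left without gained genes whose peak meets a vector peak. Values that moved are given below by setting, in the order vector then POH1-Flag cells for MYC. Comparisons that need strand, sequence or repeats were not run.

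With a −log10 q of at least 5 the lists held 1523 Flag and 6838 and 13884 MYC peaks, and 28 genes had a Flag peak near an end. MYC peaks near a gene end were 50.8% and 46.7%. Overlap was 88.4% of vector peaks and 43.4% of POH1-Flag peaks, and 43.9% of Flag peaks met POH1-Flag MYC. The median log2 pileup ratio was 0.67 near gene ends and 0.0328 at sites with a Flag peak. The loss of peaks follows from the threshold; for the rest the cause was not tested.

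With a −log10 q of at least 10 there were 479 Flag and 2162 and 6265 MYC peaks, with 14, 1512 and 4392 genes marked near an end. Near a gene end lay 3.13% of Flag and 56.6% and 58.6% of MYC peaks. Overlap was 92.7% of vector and 32.0% of POH1-Flag peaks, and 61.8% and 60.8% of Flag peaks met MYC. Of the gene lists, 9 stood above all genes in vector cells. The median log2 ratios were 0.59 and 0.0328. The loss of peaks follows from the threshold; for the rest the cause was not tested.

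With a fold of at least 5 there were 1750 Flag and 7091 and 12487 MYC peaks, 51.2% and 46.6% of the latter near a gene end. Overlap was 82.3% and 46.6% between MYC lists and 37.9% and 38.1% for Flag in MYC, 10 gene lists stood above all genes in vector cells, and the median log2 ratios were 0.69 and 0.0328. The cause was not tested beyond the loss of peaks.

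Stricter or looser overlap changes the shares by construction. An overlap of at least 50% of both peaks gave 64.1% of vector and 34.4% of POH1-Flag MYC peaks shared, and 34.8% and 37.4% of Flag peaks in MYC. Summits within 200 bp gave 70.2% and 37.7%, and 37.4% and 41.3%. Peaks within 1 kb gave 86.6% and 48.2%, and 44.8% and 50.1%. At equal list lengths 70.9% of vector peaks and 69.7% of POH1-Flag peaks were shared, 14.3% and 8.86% of Flag peaks met MYC, and the median log2 ratios were 0.74 near gene ends and 0.10 with a Flag peak; the cause was not tested.

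On chromosomes 1 to 19 and X alone, 45.3% and 36.3% of MYC peaks were near a gene end. A summit within 5 kb of a gene end raised the shares by construction to 6.95% for Flag (216 genes) and to 54.6% and 46.7% for MYC, with a median log2 ratio of 0.70. Counting any peak base within 1 kb gave 45.6% and 37.1%. After thinning to the vector depth 45.9% of POH1-Flag MYC peaks overlapped a vector peak. Without MYC peaks that meet a Flag peak, 49.2% and 37.8% were near a gene end and overlap was 85.99% and 43.8%; the cause was not tested.

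Scaling changes every pileup ratio by a constant. Scaled by reads alone the median log2 ratios were 0.59 near gene ends and −0.17 at sites with a Flag peak, and scaled to sites with a Flag peak the ratio near gene ends was 0.76.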

Other observations

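Thinning was fixed beforehand, but its bound as a test of depth, and the tests of a common scale error, of the depth of the Flag library, of Flag occupancy at gene ends and of more reads from chromosomes 1 to 3 in the Flag library were chosen after the result was seen, as was the background at gene ends on chromosomes 1 to 3.

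MYC and Flag peaks were spread differently over the chromosomes. On chromosome X, MYC had 1.22 peaks per Mb in vector cells and 2.76 in POH1-Flag cells, against 4.68 and 8.87 on chromosomes 4 to 19, while Flag had 0.837 against 0.825. MYC peaks were densest on chromosome 19 in vector cells (7.56 per Mb) and on chromosome 11 in POH1-Flag cells (13.04 per Mb). The 3 strongest peaks were the same in every library, in a different order. They lay at chromosome 9, 35305141 to 35305715, at chromosome 6, 103648974 to 103649436 and at chromosome 11, 89081617 to 89082164 in the Flag list, and those on chromosomes 6 and 11 were inside a gene. Against 10000 random lists matched on gene length, ribosomal proteins had 60 genes with a vector peak where random lists had a mean of 18.2, and the proteasome 23 where random lists had 13.7.

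More MYC peaks and higher pileups at gene ends were found in POH1-Flag than in vector cells, and after thinning to the vector depth, which was run on peak numbers and overlaps only, the list was still 1.82 times as long as the vector list. A scale error common to all sites would also lift shared sites that meet a Flag peak, where the median log2 ratio was −0.0534 (−0.08 to 0.01), although the 22 of these sites near gene ends had 0.23 (0.06 to 0.70). A better enriched MYC library in POH1-Flag cells may give the same picture as more MYC on the DNA, since in both cases pileups in excess of local background would rise by a like factor at weak and strong sites. The medians of that excess differed by 0.32 on the log2 scale over 10 bins of strength. With 1 library per cell line these cannot be told apart, and the effect of POH1-Flag itself stays open.

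Flag peaks lay away from gene ends and recurred in the MYC libraries. Lower depth is not the reason, since the Flag library had 1.05 times the depth of vector MYC. A candidate explanation for the shared sites is signal that appears with any antibody. At sites shared with MYC of vector cells, which carry the empty vector in place of POH1-Flag, the median log2 pileup ratio was 0.16 (0.12 to 0.18). These sites were called in both lists from libraries of like depth, which draws their pileups together. The 1693 Flag peaks without a vector MYC partner do not enter. POH1-Flag and MYC at the same sites could give a like value, so the explanation stays open. POH1-Flag at MYC sites near gene ends was met by a Flag peak at 0.4999% of vector sites, but occupancy too weak to be called would leave no peak, so its absence cannot be told apart from a weak signal. The 1238 Flag peaks in neither MYC list have no called partner, so the comparison of pileups does not cover them. They were weaker than Flag peaks in both MYC lists, with a median pileup of 13 against 20 reads. Whether they hold a shared signal below the MYC threshold was not tested, and no biological explanation was tested for them.

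Flag peaks were denser on chromosomes 1 to 3 than on 4 to 19, at 2.06 against 0.825 per Mb (ratio 2.49, 2.31 to 2.70), but not among the few near gene ends (9 against 33 peaks, ratio 0.976, 0.411 to 2.09), and MYC peaks away from gene ends were also denser there, at ratios of 1.40 (1.32 to 1.48) in vector and 1.15 (1.11 to 1.20) in POH1-Flag cells, whereas MYC peaks near gene ends were sparser there, at 0.841 (0.785 to 0.901) and 0.863 (0.816 to 0.912). Chromosomes 1 to 3 were the densest in Flag peaks among 1 to 19 and X, at 2.29, 2.06 and 1.76 per Mb. This grouping was not planned, and the intervals do not allow for its choice. Extra copies in both cell lines or in POH1-Flag cells alone would raise the local background of MYC in POH1-Flag cells, but its ratio at sites shared by all 3 libraries was 0.895 (0.819 to 1.0), and at gene-end MYC peaks it was 1.016 (0.992 to 1.06). In vector cells the ratios were 1.09 (1.01 to 1.20) and 1.05 (1.01 to 1.07), which alone would not exclude copies there. More reads from chromosomes 1 to 3 in the Flag library alone could add peaks there. The background ratio in that library was 1.42 (1.31 to 1.55) at Flag peaks found in neither MYC list but 1.05 (0.956 to 1.16) at the shared sites, so this stays open, and no biological explanation was tested.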
